A study of Mus musculus with 208 samples.

How the data were processed

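RNA from mouse embryonic stem cells was sequenced in 208 libraries. Poly-A RNA was made into TruSeq libraries and read from a single end on Illumina HiSeq instruments, per the labels' protocols. TopHat 1.3.3 and the genome build mm9 are named in the submitters' processing notes. The gene counter, the gene annotation and the strand setting are not given in the sources used here, so reads of a gene and of its antisense partner may not be told apart. The deposited files give unnormalised read counts for 21761 Entrez gene identifiers, with a separate file per library. Symbols were attached to 21615 identifiers from an NCBI RefSeq gene table of GRCm38.p6, used for names only, since the counts rest on mm9. Identifiers without a symbol held 0.579% of all counts. No coordinates are given for this reason.

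The groups were taken from the sample titles and labels. Each treated library combined a cell line (R1 or JM8.N4), a morphogen condition and a small molecule, with 1 library per combination. The labels give 30 h for the small molecules in the protocol and sample source and 36 h in the name of a characteristics field, and 24 h for the morphogens. No library had a morphogen without a small molecule, so each morphogen was compared with N2B27 medium across libraries that all held a small molecule, and each small molecule with the other small molecules. Each of the 10 combinations of line and morphogen is called a block below. The libraries of a block carry consecutive library numbers, and the mock libraries carry a separate number series, so a block or a mock group cannot be separated from anything else shared by its run of libraries. Each small molecule held the same place in the number run of every block it was in. Its effect therefore cannot be separated from an effect of that place.

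The main model was edgeR 4.0.16 in R 4.3.3, with quasi-likelihood F tests on TMM-normalised counts. Genes with at least 1 CPM (counts-per-million) in at least 5 libraries were kept, which left 16384 genes. The design held 1 term per block, 1 per line for mock, and additive small-molecule effects that sum to 0 over the 24 small molecules, in 35 columns with 173 residual degrees of freedom. All 208 libraries shared the estimate of the spread, because single combinations had no replicate. Morphogen effects were averaged over both line labels with equal weight. P-values were adjusted by Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold, and for the morphogens and for N2B27 against mock it also had to change in the same direction under each line label. A minimum of 1.5-fold was used for small molecules and for pairs of them. LDN-193189 and dorsomorphin were compared in a fit of the 121 libraries labelled R1, over 16084 genes, because dorsomorphin was used under that label alone. Errors of log2 fold changes are approximate standard errors (SE), the absolute change divided by the square root of its F statistic. The changes include a prior count, so these errors are rough for genes near 0 CPM. Intervals are 95% from the t distribution with 173 degrees of freedom. That number was also used for the fit of R1-labelled libraries and for the interactions, which have fewer. CPM values are given with the standard deviation (SD) over libraries. The p-values treat separate libraries as replicates. The mock libraries differed little and may be technical replicates. Since the spread came mostly from treated libraries, tests on mock libraries do not measure the spread among them.

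Genes were named by a rule fixed before the data were examined. For each morphogen, for N2B27 against mock and for the treated lines, the rule took the 6 called genes with the highest and the 6 with the lowest change among genes with a mean log2 CPM of at least 1. For each small molecule it took 3 each way with the same sign in at least 80% of its libraries, and for pairs and interactions 3 each way. It also took the members of gene lists fixed at the same time. These 30 lists covered the pluripotency core, naive and formative pluripotency, Activin and nodal targets, mesendoderm, BMP targets, FGF and ERK targets, retinoic acid targets, neural genes, primitive endoderm, trophectoderm, fibroblast markers, Zscan4 genes of the 2-cell-like state, Wnt, Notch, hedgehog, FOXO, NF-kB, Nrf2, p53, SRF and YAP, Myc and aryl hydrocarbon receptor targets, germline genes, mitosis, endoplasmic reticulum stress, metallothioneins, cholesterol synthesis, hypoxia and glycolysis, and heat shock. For each list the count of called members is given over all genes tested and adjusted over the list alone. A list score per library was the mean of log2(CPM + 1) over the list's tested genes. The score's deviation from the other libraries of the block was averaged over the libraries of each small molecule and tested with a two-sided permutation test of 100000 resamples, with small-molecule labels permuted within blocks. The p-values were adjusted over all 720 pairs of list and small molecule.

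Simulated counts were used to test that the model works as coded. They were drawn from the real N2B27 means of each line and the real library sizes, with a fixed dispersion of 0.05. Libraries of a line differed there in the planted genes alone, without clusters, fibroblast variation or wrong labels. The recovery and false calls therefore do not give the error rates on the real libraries. Genes were counted there at an adjusted p under 0.05, without the fold minimum or the rule on direction. Over 15337 genes, edgeR recovered 100%, 100% and 98.5% of genes planted at 1.5-fold, 2-fold and 4-fold in the BMP4 comparison, with 17 false calls, and 92.5%, 100% and 100% for LDN-193189, with 11 false calls. It made 0 calls for Activin A and 0 for Genistein, where nothing was planted, and limma-voom likewise made 0 and 0. A list score shift of 0.4 planted for 1 small molecule was found as 0.41 (adjusted p = 0.0024).

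Totals ranged from 8178141 to 31755361 counts per library, and normalisation factors from 0.809 to 1.193. No pair of libraries had identical counts. Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, no filter on low counts, limma-voom (limma 3.58.1), the DESeq2 Wald test, no fold minimum, no small-molecule terms, the 9 small molecules present in all 10 blocks, single lines, left-out libraries, other pseudocounts and references for the list scores, and list members with a mean of at least 5 CPM. Alternatives chosen after seeing the data were trended dispersions, a term for the expression cluster of each library, fits within each cluster, a term for the fibroblast marker score, and fits without libraries whose labels were in doubt. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the clusters and the plots. No library was left out of the main model. Some genes that the naming rule selected are not reported here.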

Results

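The series profiled RNA from mouse embryonic stem cells of lines labelled R1 and JM8.N4, which were kept without feeder cells in N2B27 medium with inhibitors of MEK, GSK3 and FGF receptors. The treated libraries combined 1 of 5 morphogen conditions with 1 of 24 small molecules. The conditions were Activin A at 20 ng/ml, bFGF at 6 ng/ml, BMP4 at 2 ng/ml, retinoic acid at 5 uM and N2B27 without a morphogen, each for 24 h. Of the libraries labelled R1, 23 were from Activin A, 24 from bFGF, 24 from BMP4, 23 from N2B27, 24 from retinoic acid and 3 from mock cells. Of those labelled JM8.N4, 14, 18, 19, 14 and 19 were treated in the same order, and 3 were mock. Single combinations had no replicate, so each small molecule was represented by 5 to 10 libraries over different blocks of line and morphogen. Total counts ran from 8178141 to 31755361 per library. The mean was lowest for R1-labelled mock, at 16638711 ± 920955 (SD, n = 3), and highest for JM8.N4-labelled mock, at 25687359 ± 5094599 (SD, n = 3).

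Several properties of the libraries bear on every comparison. Eif2s3y, a Y-linked translation factor gene, was at 60.7 CPM or more in 114 libraries and at 6.2 CPM or less in the other 94, and 31 genes split the libraries in this way, 29 of them on other chromosomes. The higher side is called cluster 1 and the lower side cluster 2. In N2B27 and bFGF the split followed the line label, with 23 and 24 R1-labelled libraries on the higher side and 14 and 18 JM8.N4-labelled ones on the lower. With BMP4, 18 of 24 R1-labelled libraries lay on the lower side and 14 of 19 JM8.N4-labelled ones on the higher. With retinoic acid the numbers were 20 of 24 and 15 of 19, and all 6 mock libraries lay on the higher side. In all, 71 libraries sat on the side at odds with their line label. Collagen and other fibroblast marker genes also varied within blocks, with a mean list score of 2.64 ± 1.38 (SD, n = 24) and a range from 0.27 to 4.54 in R1-labelled bFGF libraries. The score was 1.03 ± 0.35 in R1-labelled N2B27 (SD, n = 23) and 5.13 ± 0.06 in R1-labelled mock (SD, n = 3). For 4 libraries the responses of p53 or Wnt targets sat under another small-molecule label of the same run.

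**Figure D1:**
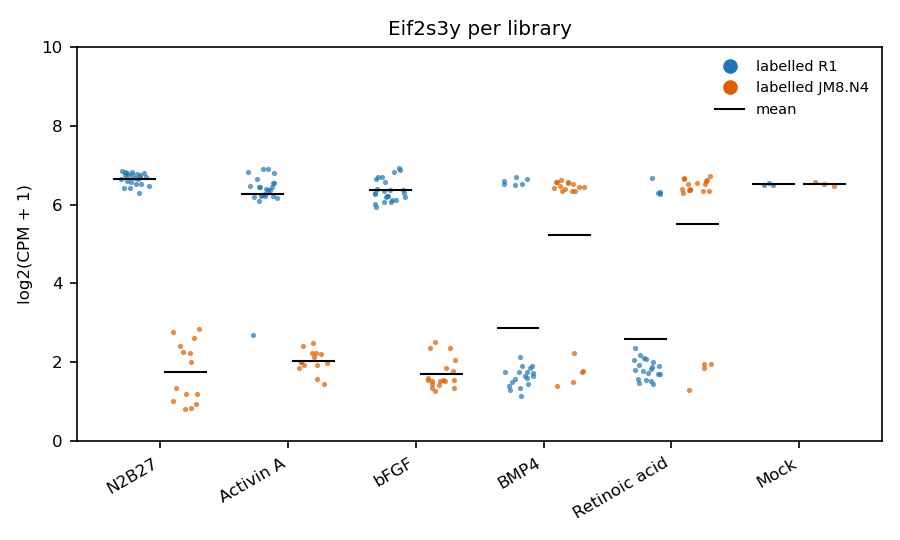
Expression of Eif2s3y as log2(CPM + 1) on the vertical axis for each library, by morphogen condition and line label, with the mean of each group as a bar. The 114 libraries at 60.7 CPM or more and the 94 at 6.2 CPM or less include both line labels in BMP4 and in retinoic acid.

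**Figure D2:**
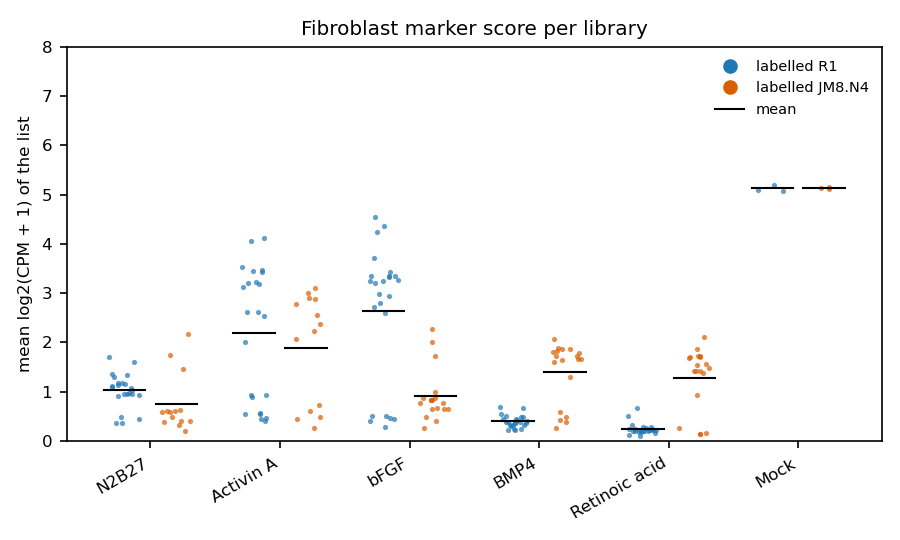
Mean log2(CPM + 1) of the fibroblast marker list on the vertical axis for each library, by morphogen condition and line label, with the mean of each group as a bar. R1-labelled bFGF libraries ran from 0.27 to 4.54, and mock libraries lay above 5.

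Retinoic acid was compared with N2B27 to find the genes that this inducer of differentiation changes. Cyp26a1 (Entrez 13082), which encodes the enzyme that breaks down retinoic acid, rose by 9.84 ± 0.17 log2 (SE, adjusted p = 1.81e-151). Its mean was 0.15 ± 0.15 CPM in N2B27 and 94.6 ± 51.7 CPM with retinoic acid under the R1 label (SD, n = 23 and 24), and 0.11 ± 0.09 and 160 ± 44.6 CPM under the JM8.N4 label (SD, n = 14 and 19). Among the rule-named genes Hoxa5 (Entrez 15402), a homeobox gene, rose by 7.62 ± 0.18 log2, Hoxb2 (Entrez 103889) by 7.54 ± 0.20, Hoxb4 (Entrez 15412) by 6.73 ± 0.18 and Hoxb3 (Entrez 15410) by 6.58 ± 0.22. Hoxaas3, at 6.60 ± 0.18, is antisense to Hox genes and its reads may not be told apart from theirs. Otx2 (Entrez 18424), a transcription factor gene of the forebrain and of formative pluripotency, changed by -5.21 ± 0.28 log2, from 49.3 ± 29.0 to 0.69 ± 0.50 CPM under the R1 label (SD). Vrtn (Entrez 432677) changed by -3.88 ± 0.35 log2, Enpp2 (Entrez 18606) by -3.59 ± 0.28, Col3a1 by -3.17 ± 0.66, Ly6g6e by -3.07 ± 0.25 and Slc27a2 by -2.93 ± 0.15.

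By list, 13 of 15 retinoic acid targets rose over all genes and 13 adjusted over the list alone, with Stra8 at 5.90 ± 0.20 log2. Rarb, at 0.26 ± 0.03, and Crabp2, at -0.09 ± 0.12, did not pass. Of 12 primitive endoderm genes 8 rose (8 adjusted over the list alone), among them Gata6 at 4.04 ± 0.26, Gata4 at 2.44 ± 0.20 and Sox17 at 2.58 ± 0.31 log2. Scores of this list were high in JM8.N4-labelled cluster 1 libraries alone, at 5.48 or more against 3.61 or less in the other retinoic acid libraries. Of 9 mesendoderm genes 5 rose (5 adjusted over the list alone), and of 11 germline genes 5 rose (5 adjusted over the list alone). All 3 Zscan4 genes tested, which mark the 2-cell-like state and belong to a multi-copy family whose reads may be shared, rose with a median of 2.48. Of 8 formative genes 4 fell (4 adjusted over the list alone), with Dnmt3b at -2.18 ± 0.15 and Fgf5 at -1.96 ± 0.17. Of 14 naive genes 2 fell, Tcl1 at -1.55 ± 0.13 and Nr0b1 at -1.01 ± 0.08, while Nanog stood at 0.20 ± 0.09. In edgeR 0 of 5 pluripotency core genes passed the 2-fold minimum, with 5 at an unadjusted p under 0.05, 0 in limma-voom and in DESeq2, and Pou5f1 at -0.51 ± 0.04. Of 8 fibroblast markers 3 fell (3 adjusted over the list alone), Col3a1, Lum and Thy1. In all 1565 genes were called, 1182 up and 383 down.

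**Figure D3:**
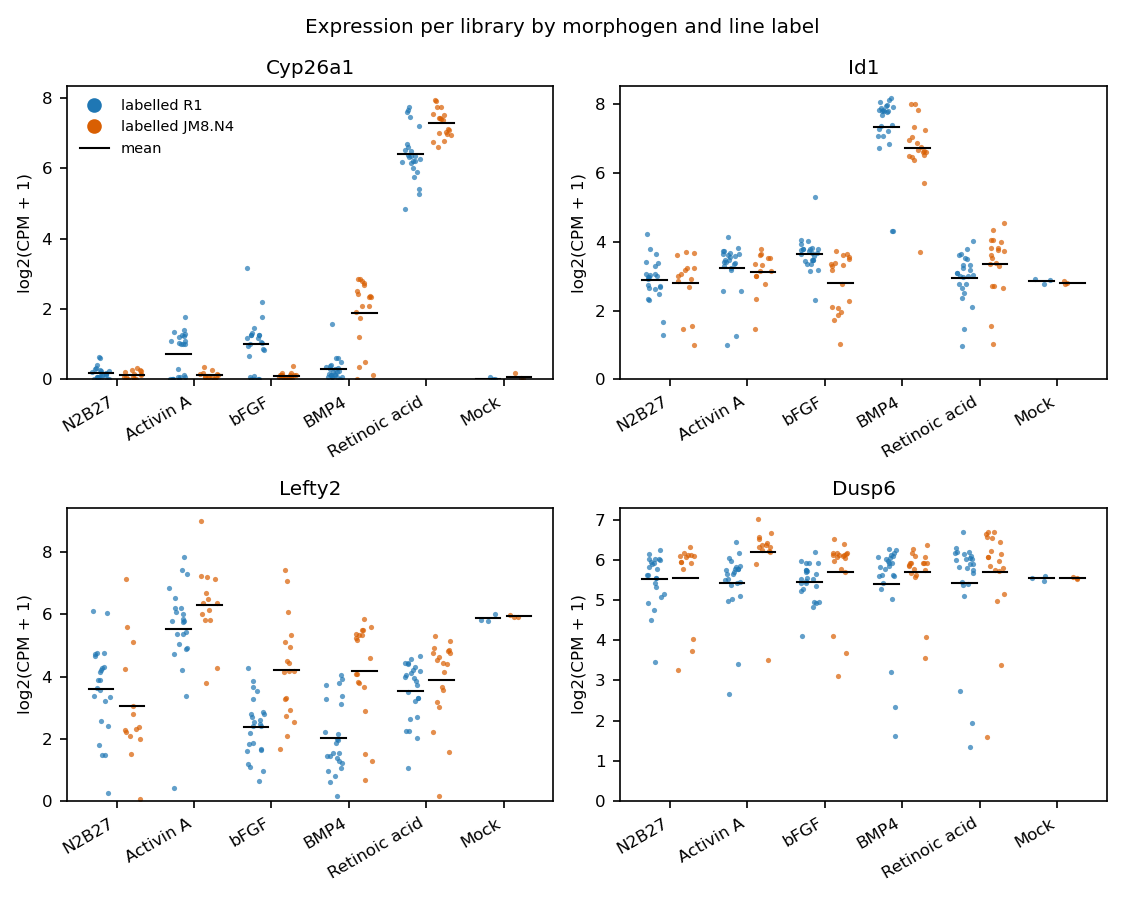
Expression of Cyp26a1, Id1, Lefty2 and Dusp6 as log2(CPM + 1) on the vertical axes for each library, by morphogen condition and line label, with the mean of each group as a bar. Cyp26a1 was highest with retinoic acid, where its mean was 94.6 CPM under the R1 label, and Id1 was highest with BMP4, at 188 CPM.

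BMP4 was compared with N2B27 in the same way. Id1 (Entrez 15901), a direct BMP target that blocks differentiation factors, rose by 4.47 ± 0.16 log2 (SE, adjusted p = 4.02e-62), from 7.06 ± 3.54 to 188 ± 73.1 CPM under the R1 label (SD, n = 23 and 24) and from 6.94 ± 3.54 to 122 ± 63.8 CPM under the JM8.N4 label (SD, n = 14 and 19). Coch (Entrez 12810) rose by 4.35 ± 0.15 log2, Id2 (Entrez 15902) by 3.66 ± 0.16, Msx2 by 2.97 ± 0.20, Cyp26a1 by 2.83 ± 0.42 and Gata2 (Entrez 14461) by 2.75 ± 0.27. Of 9 BMP targets 6 rose over all genes and 6 adjusted over the list alone, with a median of 2.38, including Id3 at 2.38 ± 0.18, Msx1 at 2.75 ± 0.16 and Smad6 at 1.33 ± 0.08. Col3a1, at -3.09 ± 0.60 log2, Enpp2, at -1.97 ± 0.23, Dcn, at -1.72 ± 0.60, Ccdc136 (Entrez 232664), at -1.59 ± 0.13, Wt1, at -1.54 ± 0.20, and Igfbp5, at -1.49 ± 0.30, fell. Col3a1 and Dcn are fibroblast markers, of which 3 of 8 fell.

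Genes of extraembryonic lineages moved too. Of 12 primitive endoderm genes 7 rose (7 adjusted over the list alone), with Sox17 at 2.95 ± 0.30, Sox7 at 2.65 ± 0.19 and Gata4 at 2.04 ± 0.21 log2. Gata4 went from 1.52 ± 0.79 to 22.8 ± 12.9 CPM under the JM8.N4 label (SD, n = 14 and 19) and from 1.72 ± 0.74 to 2.18 ± 1.13 CPM under the R1 label (SD, n = 23 and 24). Primitive endoderm scores were 5.59 or more in the 14 JM8.N4-labelled cluster 1 libraries with BMP4 and 3.68 or less in the others. Of 9 trophectoderm genes 4 rose (4 adjusted over the list alone), with Hand1 at 2.96 ± 0.24, Gata3 at 2.24 ± 0.23 and Cdx2 at 1.52 ± 0.20. Of 9 mesendoderm genes 3 rose, Sox17, Evx1 and Wnt3 (3 adjusted over the list alone). In edgeR 0 of 14 naive genes were called, with 6 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. The test called 153 genes, 130 up and 23 down. It called 91 without the 71 libraries at odds with their line label, 96 over the small molecules present in every block, 1260 from R1-labelled and 1267 from JM8.N4-labelled libraries alone. Within each label most BMP4 libraries lay in the other cluster than the N2B27 ones, so these single-label counts also hold cluster differences.

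Activin A was compared with N2B27. Lefty2 (Entrez 320202), a secreted inhibitor of nodal signalling, rose by 2.48 ± 0.25 log2 (SE, adjusted p = 9.76e-16), from 17.3 ± 17.6 to 66.2 ± 55.1 CPM under the R1 label (SD, n = 23 and 23) and from 19.8 ± 37.6 to 112 ± 121 CPM under the JM8.N4 label (SD, n = 14 and 14). Lefty1 (Entrez 13590) rose by 2.30 ± 0.26 and Smad7 (Entrez 17131) by 1.40 ± 0.10 log2. With the other members, which included Nodal at 0.20 ± 0.09 and Skil at 0.42 ± 0.10, 4 of 8 Activin and nodal targets rose over all genes and 4 adjusted over the list alone. Among the rule-named genes Lox (Entrez 16948), which crosslinks collagen, rose by 4.50 ± 0.43 log2, Acta2 (Entrez 11475), smooth muscle actin, by 4.44 ± 0.37, Tnc (Entrez 21923) by 4.15 ± 0.36, Col1a1 (Entrez 12842) by 4.05 ± 0.38, Thbs1 by 3.98 ± 0.36 and Bgn by 3.91 ± 0.47. Otx2 was the sole rule-named gene that fell, at -1.01 ± 0.20.

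By list, 7 of 8 fibroblast markers rose (7 adjusted over the list alone, median 2.71), as did 6 of 12 SRF and YAP targets (6 adjusted over the list alone) and 4 of 12 primitive endoderm genes (5 adjusted over the list alone). All 3 Zscan4 genes rose, with Zscan4c at 1.78 ± 0.33. Col1a1 varied widely between libraries, at 30.2 ± 31.2 CPM with Activin A under the R1 label (SD, n = 23). With the fibroblast marker score of each library as a term, a test added after seeing the data, Lox stood at 0.61 (adjusted p = 0.167), Acta2 at 0.78 (0.151) and Zscan4c at 0.12. Lefty2 stood at 2.81 and Lefty1 at 2.40. That term removes genes that vary with the score by construction, whatever their source. These values therefore do not show whether Activin A raised such genes. The call count was 415, 409 up and 6 down, and 66 with that term. In edgeR 0 of 14 naive genes and 0 of 5 pluripotency core genes were called, with 4 and 1 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. Nanog stood at 0.17 ± 0.09 and Pou5f1 at -0.06 ± 0.05.

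With bFGF the list of FGF and ERK targets showed no call. In edgeR 0 of 11 passed over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. Dusp6, a phosphatase gene induced by ERK, stood at 0.03 ± 0.12 log2 (95% interval -0.20 to 0.26), Spry4 at 0.08 ± 0.13 and Etv4 at 0.30 ± 0.12 (adjusted p = 0.0852). The rule-named genes that rose were Lox at 2.75 ± 0.75 (SE, adjusted p = 0.00873), Col1a2 (Entrez 12843) at 2.55 ± 0.57, Col1a1 at 2.37 ± 0.47, Bgn at 2.29 ± 0.80, Tnc at 2.20 ± 0.41 and Dcn (Entrez 13179) at 2.13 ± 0.40. Cyp1a1 (Entrez 13076), at -1.30 ± 0.36, the iron exporter gene Slc40a1 (Entrez 53945), at -1.16 ± 0.20, and Zfp36l3 (Entrez 333473), at -1.05 ± 0.31, fell. Of 8 fibroblast markers 5 rose (5 adjusted over the list alone, median 1.91). Their rise stood under the R1 label, with Col1a2 at 5.04 against 0.06 log2 under the JM8.N4 label. The fibroblast score as a term, which removes such genes by construction whatever their source, left Lox at 0.24. The test called 71 genes, 59 up and 12 down, but 12 with that term, 24 over the small molecules present in every block, 34 in limma-voom and 43 without small-molecule terms.

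N2B27 with small molecules was set against mock cells. Formative pluripotency genes were higher in N2B27, with 7 of 8 up over all genes and 7 adjusted over the list alone. Pou3f1 was up by 4.08 ± 0.57 log2 (SE), Otx2 by 2.76 ± 0.47, Dnmt3a by 2.49 and Dnmt3b by 2.49, while Fgf5 was lower at -1.36 ± 0.20. Of 14 naive genes 6 were lower (6 adjusted over the list alone), including Tbx3 at -2.37 ± 0.21, Tfcp2l1 at -2.15 ± 0.17 and Klf4 at -1.16, and Dppa3 was higher at 2.57. Of 13 Wnt targets 7 were lower (7 adjusted over the list alone), with Sp5 at -5.45 ± 0.23, Cdx1 at -4.98 and Axin2 at -2.31. Pou5f1 stood at 0.04 ± 0.08, and 2 of 5 core genes were higher, Utf1 at 1.37 ± 0.26 and Lin28a at 1.39 ± 0.23. Of 4 hedgehog targets 3 were higher, and Pax6 (Entrez 18508), a neural transcription factor gene, was higher by 5.80 ± 0.85 (adjusted p = 8.97e-10). Vrtn (4.72 ± 0.93), Foxr2 (4.64 ± 0.47), Esrp1 (4.56 ± 0.57) and the microRNA gene Mir142 (4.66 ± 1.01, uncertain in poly-A libraries) were also named by the rule.

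The genes highest in mock against N2B27 were fibroblast genes, 7 of 8 of the list (7 adjusted over the list alone, median -6.95). Lox stood at -8.31 ± 0.36 log2, Bgn at -8.00 ± 0.36, Col1a2 at -7.82 ± 0.38, Dcn at -7.74 ± 0.24, Col1a1 at -6.78 ± 0.42 and Col12a1 at -6.22 ± 0.38. Col1a2 was at 203 ± 9.83 CPM in R1-labelled and 203 ± 9.37 CPM in JM8.N4-labelled mock (SD, n = 3 each), and at 1.43 ± 1.09 CPM in R1-labelled N2B27 (SD, n = 23). Of 12 primitive endoderm genes 7 and of 9 trophectoderm genes 4 were also lower in N2B27. The test called 2763 genes, 962 up and 1801 down. With the fibroblast score as a term it called 2556, of which 1438 were among the 2763. The mock libraries differ from the N2B27 ones in library series as well as in treatment. Under the JM8.N4 label they differ in cluster too, with all 3 mock libraries in cluster 1 and all 14 N2B27 ones in cluster 2. The changes averaged over both labels therefore also hold cluster differences.

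Line labels were compared next. Among treated libraries Olig2 (Entrez 50913), an oligodendrocyte lineage factor gene, was lower under the R1 label, at -4.53 ± 0.39 log2, and Cysltr2 (Entrez 70086) was higher by 4.59 ± 0.54. In N2B27 Olig2 was at 0.04 ± 0.07 CPM under R1 (SD, n = 23) and 56.3 ± 13.4 CPM under JM8.N4 (SD, n = 14). With BMP4 it was at 37.6 ± 24.4 and 11.7 ± 20.5 CPM (SD, n = 24 and 19). Cysltr2 was at 0.00 CPM in JM8.N4-labelled N2B27, so its fitted size depends on the prior count. Also higher were Mir692-1 (3.82 ± 0.34, a microRNA gene), Ly6a (3.09 ± 0.26), Arhgef38 (2.85 ± 0.27), Kbtbd11 (2.78 ± 0.31) and Lrrc46 (2.37 ± 0.24). Lower were Ubd (-4.17 ± 0.47), Apoa2 (-3.62 ± 0.31), Acta2 (-2.98 ± 0.37), Olig1 (-2.74 ± 0.24) and Col3a1 (-2.71 ± 0.36). All 3 Zscan4 genes were higher (median 1.69), and 6 of 12 primitive endoderm genes were lower (6 adjusted over the list alone), as were 3 of 9 trophectoderm genes. The test called 451 genes, 246 higher and 205 lower, and with the cluster of each library as a term Olig2 stood at -0.12 and Cysltr2 at 0.66. Between the mock libraries of the 2 labels edgeR called 0 genes, with 30 at an unadjusted p under 0.05, 0 in limma-voom and 2 in DESeq2. The spread in that test came mostly from treated libraries, so the low counts do not show that the mock labels are alike.

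Responses to every morphogen differed between the line labels. With BMP4, 10 of 12 primitive endoderm genes responded less under the R1 label and 2 more, with a median difference of -3.37, while 4 of 9 BMP targets (Id2, Id3, Msx1 and Msx2) and 5 of 9 trophectoderm genes responded more. With retinoic acid 9 of 12 primitive endoderm genes responded less and 2 more, and 4 of 6 neural genes (Sox1, Nes, Tubb3 and Map2) responded more. These list counts were equal when adjusted over the list alone. They go by line label, and with the cluster as a term 0 of 12 primitive endoderm genes responded less to either (median difference -0.23 with BMP4 and 0.07 with retinoic acid, with 3 and 0 at an unadjusted p under 0.05 in edgeR, and no other tool run with that term). With that term 1 primitive endoderm gene, 1 BMP target and 3 trophectoderm genes responded more to BMP4 and 1 BMP target less, and edgeR called 0 of 6 neural genes for retinoic acid, with 3 at an unadjusted p under 0.05. That term is additive, and the primitive endoderm score, a mean log2(CPM + 1), followed neither the line label nor the cluster alone. With BMP4 it was 5.95 ± 0.23 in JM8.N4-labelled cluster 1 libraries (SD, n = 14), 2.98 ± 0.17 in JM8.N4-labelled cluster 2 (n = 5), 2.61 ± 0.36 in R1-labelled cluster 1 (n = 6) and 3.00 ± 0.27 in R1-labelled cluster 2 (n = 18). With retinoic acid it was 5.89 ± 0.20 (n = 15), 3.04 ± 0.28 (n = 4), 2.98 ± 0.19 (n = 4) and 2.95 ± 0.21 (n = 20) in the same order. The named genes of both interactions were Olig2, Ubd and Apoa2, higher, and Cysltr2, Mir692-1 and Kbtbd11, lower. They are at or near 0 CPM in some groups, so their fitted sizes depend on the prior count. With the cluster as a term the Olig2 difference for BMP4 was 1.23 against 13.10 ± 1.03 (SE) without it. With Activin A the largest differences included Nxf7 (4.22 ± 0.74), Drd3 (3.34 ± 0.47) and Gata2 (3.02 ± 0.72), and on the lower side Egr1 (-2.91 ± 0.55) and Filip1l (-2.50 ± 0.51). With bFGF they included Nxf7 (6.38 ± 0.73), Cyp1b1 (5.31 ± 0.59) and H19 (5.21 ± 0.63), and on the lower side Rac2 (-2.34 ± 0.27) and Lefty1 (-2.23 ± 0.56). The calls numbered 414 for Activin A, 1544 for bFGF, 3276 for BMP4 and 3574 for retinoic acid. With the cluster as a term they numbered 473, 1591, 680 and 297. For Activin A limma-voom called 225, the fit without small-molecule terms 172 and that over the small molecules present in every block 76, and for bFGF the last called 782 and the fit with the fibroblast score as a term 956.

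Each small molecule was then compared with the others, so a change shared by all of them cannot be seen. Each also kept the same place in its runs, so an effect of that place cannot be told apart from its own. The model called 27688 pairs of gene and small molecule, 17280 up and 10408 down, over 8411 genes. Docetaxel changed 4936 genes, Wnt agonist 3835, BIO 3712, Y-27632 2501, Olomoucine 2003, PD173074 1838, CHIR99021 1760 and the inhibitor of NF-kB activation 1691. Telomerase Inhibitor 3 changed 784 genes, SB202190 744, BAPTA-AM 698, Genistein 634, Bix01294 496, Valproic Acid 390, dorsomorphin 340, DAPT 278, Wortmannin 254, SU5402 240 and LDN-193189 200. Purmorphamine changed 124, Src Inhibitor II 115, PF573228 98 and the inhibitor of Myc dimerisation 17. These inhibitors of NF-kB activation and of Myc dimerisation are described here by their action, and their label names stand in the heat map of list scores. Leaving out single libraries gave 48 to 477 for dorsomorphin, with 48, 214 and 101 without Activin A, bFGF and retinoic acid, and 1661 for Y-27632 without BMP4. Without the 4 libraries of doubted label Purmorphamine changed 237 genes, of which 42 were among the 124, and Src Inhibitor II 190, of which 114 were among the 115. For KAAD-Cyclopamine edgeR called 0, with 2161 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. In the list scores 73 of 720 pairs of list and small molecule passed, 40 up and 33 down, in permutation tests.

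**Figure D4:**
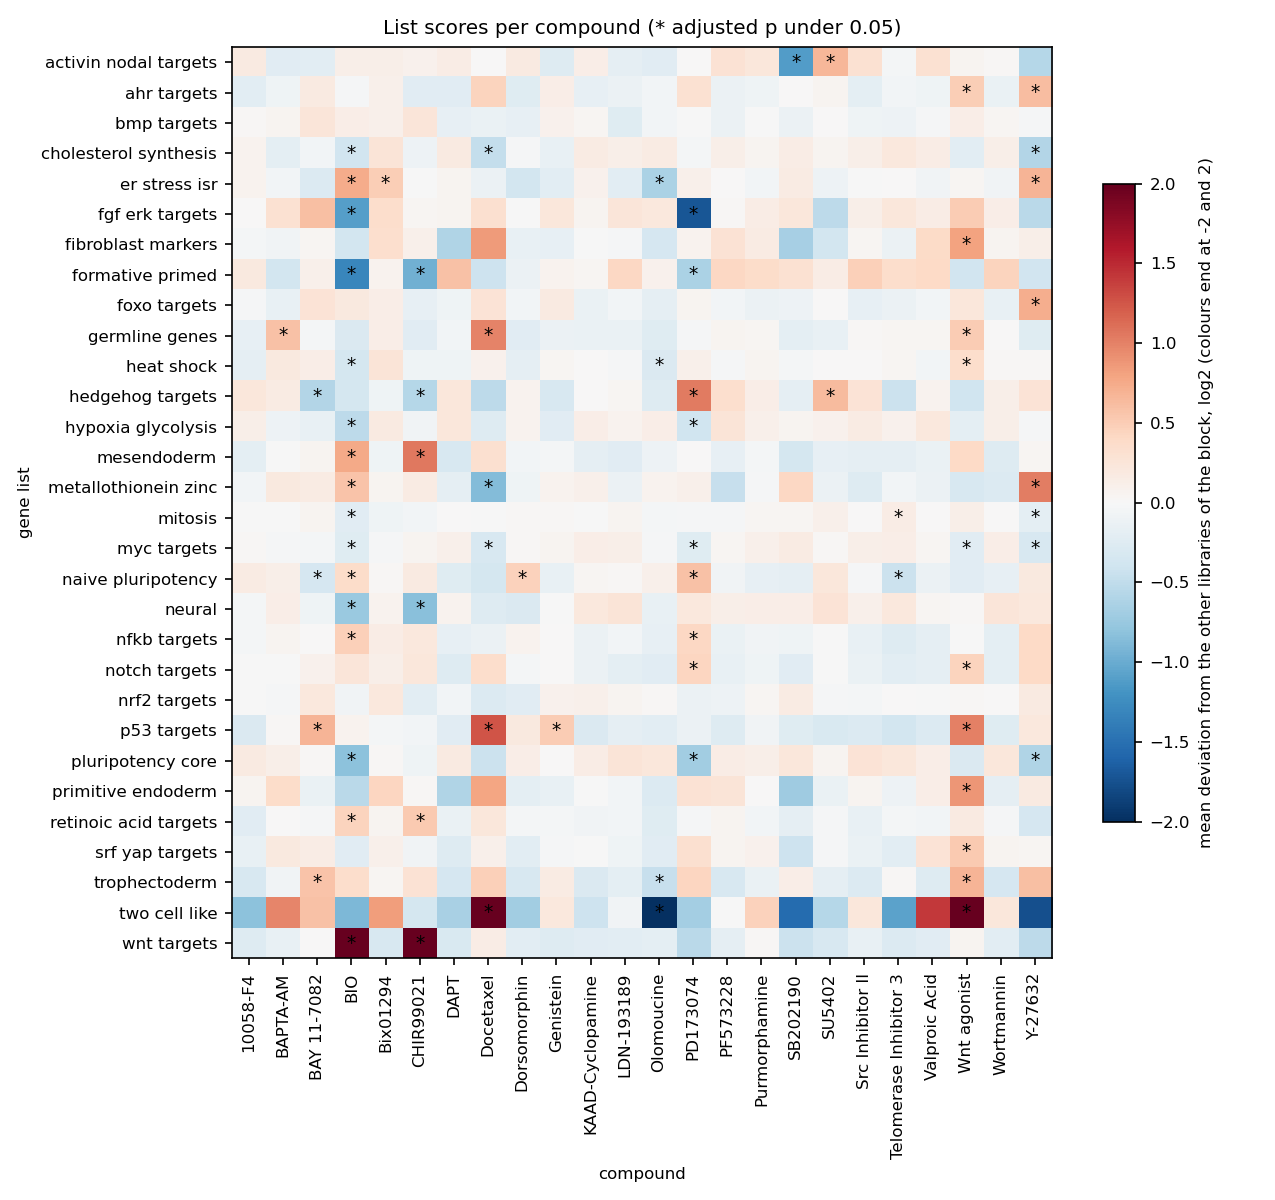
Mean deviation of each gene list score from the other libraries of its block, in log2 units as colour, for the 30 lists and 24 small molecules, with asterisks at an adjusted p under 0.05. Wnt targets were up under CHIR99021 and BIO, at 2.01 and 2.15, and FGF and ERK targets down under PD173074, at -1.71.

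CHIR99021 at 3 uM and BIO at 500 nM both inhibit GSK3, the kinase that marks beta-catenin for breakdown. Under CHIR99021 the Wnt targets T (Entrez 20997), Sp5 (Entrez 64406) and Cdx1 (Entrez 12590) rose by 6.88 ± 0.13, 6.86 ± 0.13 and 6.30 ± 0.19 log2 (SE, n = 10), and Axin2 (Entrez 12006), a feedback inhibitor of the pathway, by 3.49 ± 0.12. Under BIO Sp5 rose by 7.08 ± 0.14, Cdx1 by 5.71 ± 0.20, T by 5.57 ± 0.17 and Axin2 by 3.66 ± 0.12 (SE, n = 9). Of 13 Wnt targets 10 rose under each (10 adjusted over the list alone), and Lgr5 fell under BIO. The list scores were 2.01 ± 0.94 (9 of 10 libraries) and 2.15 ± 0.21 (9 of 9), each with an adjusted permutation p of 0.0003, the smallest these permutations can give. Formative genes fell, 6 of 8 under CHIR99021 and 8 of 8 under BIO, and mesendoderm genes rose, 5 and 6 of 9. Srms (-2.85 ± 0.43), Rassf4 (-2.41 ± 0.30) and Pax6 (-2.23 ± 0.31) fell under CHIR99021, and Enpp3 (-4.60 ± 0.42), Pdyn (-4.59 ± 0.45) and Myrf (-4.56 ± 0.46) under BIO. Under BIO 8 of 14 naive genes rose and 2 fell, 7 of 11 FGF and ERK targets fell and 7 of 10 endoplasmic reticulum stress genes rose.

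Set side by side, the inhibitors differed in 1614 genes, 663 higher under CHIR99021 and 951 higher under BIO, with doses that differ. The FGF and ERK targets Etv4 (3.07 ± 0.27 log2, 95% interval 2.54 to 3.6) and Spry4 (3.05 ± 0.30, 2.45 to 3.65) and the opioid precursor gene Pdyn (3.24 ± 0.66, 1.94 to 4.55) were higher under CHIR99021. Aspa (-2.81 ± 0.33), Fbln5 (-2.59 ± 0.42) and Hhip (-2.57 ± 0.40) were higher under BIO. Among Wnt targets T (1.25 ± 0.19) and Cdx2 (0.68 ± 0.17) were higher under CHIR99021 and Notum (-0.99) and Sp8 (-1.07) under BIO, with 2 each way adjusted over the list alone. Axin2 differed by -0.16 ± 0.20 (95% interval -0.56 to 0.25), which did not pass. Without the 71 libraries at odds with their line label 947 genes differed.

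**Figure D5:**
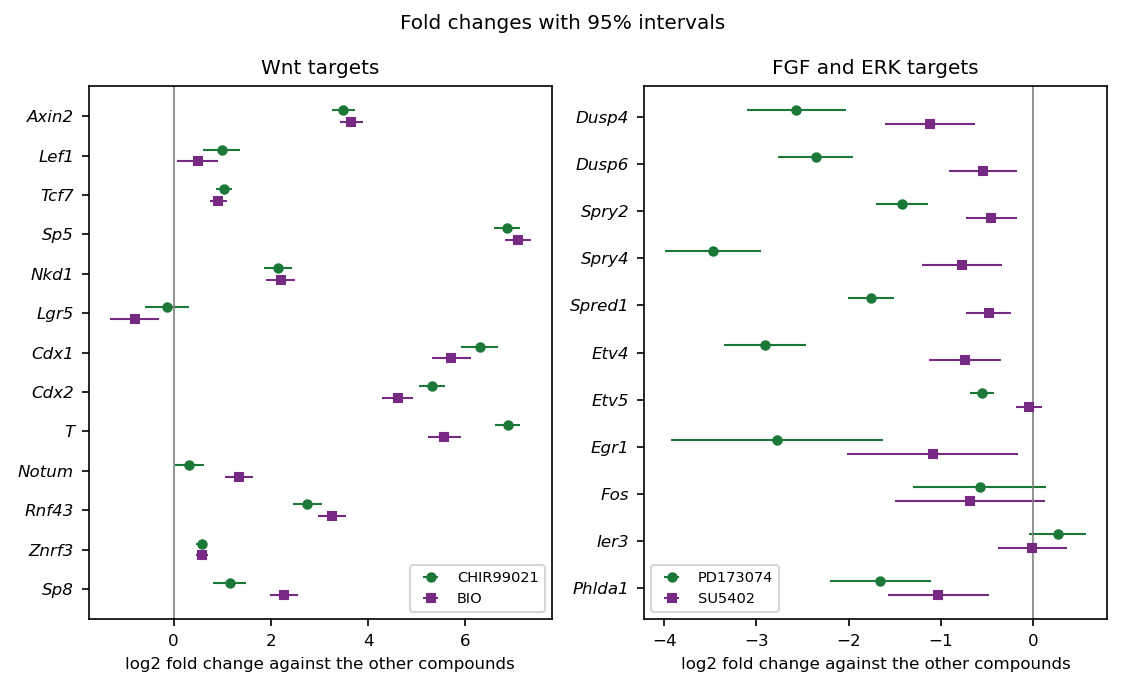
Log2 fold changes against the other small molecules, with 95% intervals as bars on the horizontal axes, for Wnt targets under CHIR99021 and BIO and for FGF and ERK targets under PD173074 and SU5402. Axin2 stood at 3.49 and 3.66 under the GSK3 inhibitors, and Spry4 at -3.47 under PD173074 and -0.77 under SU5402.

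PD173074 at 600 nM and SU5402 at 2 uM both inhibit FGF receptors. Under PD173074 Spry4 (Entrez 24066), a feedback inhibitor of FGF signalling, changed by -3.47 ± 0.26 log2, from 79.9 ± 30.2 CPM in the other libraries of its blocks (SD, n = 192) to 6.65 ± 13.4 CPM (SD, n = 10). Etv4 stood at -2.91 ± 0.23 and Dusp6 at -2.36 ± 0.21, and 8 of 11 FGF and ERK targets fell (8 adjusted over the list alone). The list score was -1.71 ± 0.50 in 10 of 10 libraries (adjusted permutation p = 0.0003, the smallest they can give). Naive genes rose, 8 of 14, as did 3 of 4 hedgehog targets, and 4 of 8 formative and 2 of 5 core genes fell. The rule also named Lrrc15 (3.56 ± 0.19), Dio3 (3.19 ± 0.16), Hesx1 (3.06 ± 0.17), Nt5e (-3.30 ± 0.31) and Vrtn (-3.17 ± 0.60). Under SU5402 4 of 11 FGF and ERK targets fell (5 adjusted over the list alone), Dusp4 at -1.12, Phlda1 at -1.02, Spry4 at -0.77 and Etv4 at -0.74, and the list score of -0.52 ± 0.29 in 8 of 8 libraries did not pass (adjusted permutation p = 0.117). Lefty1 (2.31 ± 0.28), Rassf4 (1.73 ± 0.15) and Lefty2 (1.72 ± 0.30) rose under SU5402 with 3 of 8 Activin and nodal targets, and Wnt8a (-1.69 ± 0.47), Epha1 (-1.54 ± 0.32) and Sema6a (-1.23 ± 0.38) fell.

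Between these inhibitors, whose doses differ, 6 of 11 FGF and ERK targets were lower under PD173074 (6 adjusted over the list alone), with Spry4 at -2.59 ± 0.31 (95% interval -3.21 to -1.97), Etv4 at -2.08 and Dusp6 at -1.75. Vrtn (-3.17 ± 0.76) and Nt5e (-2.08 ± 0.43) were lower and AA467197 (3.17 ± 0.44), Lox (2.58 ± 0.63) and Bgn (2.38 ± 0.78) higher under PD173074. With the fibroblast score as a term Lox stood at 0.74 and Bgn at 0.44. The pair differed in 1093 genes, 832 higher and 261 lower under PD173074, and in 507 without the 71 libraries at odds. The effect of both inhibitors in bFGF, tested against their effect elsewhere on 4 libraries, gave 99 calls, led by the fibroblast genes Col1a2 (-6.68 ± 1.26), Bgn (-6.46 ± 1.37) and Col6a1 (-5.49 ± 1.19), with Trh (1.91 ± 0.41), Gna14 (1.56 ± 0.41) and Spry4 (1.51 ± 0.38) on the other side. With the fibroblast score as a term edgeR called 0 genes, with 484 at an unadjusted p under 0.05 and no other tool run with that term, which removes fibroblast genes by construction, so this does not show their source. Of the FGF and ERK targets 1 of 11 was called (2 adjusted over the list alone), and the count was 0 without the R1-labelled PD173074 library, whose profile over 2000 genes did not match that small molecule (correlation 0.146), and 296 without the JM8.N4-labelled SU5402 library.

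LDN-193189 at 600 nM and dorsomorphin at 1 uM are BMP receptor inhibitors that share a pyrazolopyrimidine core. In BMP4 medium Id1 was at 18.9 CPM with either of them under the R1 label and at 12.1 CPM with LDN-193189 under the JM8.N4 label, and the next lowest was 51.7 CPM with Purmorphamine. Compared with their effect elsewhere, the effect in BMP4 on Id1 differed by -3.60 ± 0.39 log2 (95% interval -4.36 to -2.83, adjusted p = 9.23e-13), with Coch at -3.78 ± 0.45 and Gata2 at -4.41 ± 0.89. Of 9 BMP targets 6 were lower (7 adjusted over the list alone), with Id2 at -3.57, Msx1 at -2.90, Id3 at -2.89, Msx2 at -2.85 and Smad6 at -1.02. Ccdc136 (1.79 ± 0.30), which fell with BMP4 against N2B27, Nsg2 (1.63 ± 0.29) and the antisense gene Nphs1os (1.25 ± 0.30) were higher. This interaction rested on 3 libraries and called 24 genes, 12 in limma-voom and 15 without the dorsomorphin library.

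Averaged over all media, LDN-193189 lowered 1 of 9 BMP targets, Id4 at -0.82, and raised the neural gene Sox1 (1.29 ± 0.19, SE, n = 10), its overlapping transcript Sox1ot (1.28 ± 0.18) and Wt1 (1.13 ± 0.23). Cyp26b1 (-1.83 ± 0.52), Ly6a (-1.53 ± 0.51) and Dmgdh (-1.24 ± 0.40) fell. Dorsomorphin lowered 2 of 9 BMP targets, Id2 (-1.93 ± 0.54) and Msx1 (-1.54), with Piwil4 (-1.40 ± 0.45) and Ascl2 (-1.21 ± 0.37), and raised Grin1 (1.91 ± 0.34), A2m (1.23 ± 0.27), Hcrtr2 (1.22 ± 0.22, SE, n = 5) and 3 of 14 naive genes (5 adjusted over the list alone). Under the R1 label the pair differed in 32 genes at their different doses, including Prph (1.23 ± 0.30), Eno3 (1.19 ± 0.29), Rcn3 (1.10 ± 0.28), Xaf1 (-2.01 ± 0.48), Ak4 (-1.48 ± 0.32) and Scn3a (-1.25 ± 0.24). For BMP targets edgeR called 0 of 9 over all genes, with 2 at an unadjusted p under 0.05, 2 lower adjusted over the list alone and 0 in limma-voom. Id1 differed by 0.27 ± 0.44 (95% interval -0.60 to 1.14). The count of 32 was 4 without the Activin A dorsomorphin library and 169 without the N2B27 one.

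Docetaxel at 2.5 nM, which stabilises microtubules, and Wnt agonist at 40 nM moved several lists in the same direction. All Docetaxel libraries, 5 labelled R1 and 1 labelled JM8.N4, lay in cluster 1. Its effect is therefore partly confounded with the cluster in BMP4 and retinoic acid, whose blocks hold both clusters. Under Docetaxel the p53 target Mdm2 (Entrez 17246) rose by 2.19 ± 0.15 log2 (SE, n = 6), Perp by 2.64, Trp53inp1 by 1.69, Eda2r by 1.46 and Ccng1 by 1.44, and Cdkn1a stood at 0.78. Of 12 p53 targets 9 rose under each (9 adjusted over the list alone), with list scores of 1.26 ± 0.13 in 6 of 6 libraries (adjusted permutation p = 0.0003, the smallest they can give) and 1.00 ± 0.56 in 7 of 8 (0.000514). All 3 Zscan4 genes rose under both, with scores of 3.63 ± 0.79 and 3.12, and germline genes rose, 10 and 5 of 11. Arhgef33 rose by 3.89 ± 0.23 and 4.12 ± 0.20, Cpz under Docetaxel by 3.90 ± 0.25, and the multi-copy genes Pramel19 under Docetaxel by 3.96 ± 0.24 and Pramel39 and Pramel37 under Wnt agonist by 3.92 ± 0.26 and 3.80 ± 0.22. Under Docetaxel Ubd (-6.91 ± 2.08), Apoa2 (-6.74 ± 1.68) and Olig2 (-6.17 ± 1.60) fell, genes that follow the line split, and with the cluster as a term they stood at 1.3, 0.27 and 1.72. They were near 0 CPM under Docetaxel, so their fitted sizes depend on the prior count. Under Wnt agonist Vrtn (-1.55 ± 0.54), Slfn9 (-1.43 ± 0.32) and Gm10639 (-1.39 ± 0.47) fell.

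Fibroblast markers rose under both, 7 of 8 each, with list scores of 0.85 ± 0.79 (adjusted permutation p = 0.0851) and 0.80 ± 0.74 (0.0287). Primitive endoderm genes rose too, 8 and 10 of 12. Under Wnt agonist 6 of 9 trophectoderm genes (7 adjusted over the list alone) and 8 of 12 SRF and YAP targets rose. Of 13 Wnt targets, however, 3 rose under Wnt agonist, Rnf43 at 1.22, Sp5 at 1.20 and Lgr5 at 0.84, and 2 fell, Notum at -0.75 and Lef1 at -0.64, with a list score of 0.06 ± 0.23 (adjusted permutation p = 0.954). Mitosis genes showed 0 calls of 10 under Docetaxel in edgeR, with 6 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2.

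The compound at 20 uM sold as an inhibitor of NF-kB activation, and Genistein at 10 uM, a tyrosine kinase inhibitor, both raised Wnt8a, by 3.30 ± 0.21 (SE, n = 8) and 2.17 ± 0.24 (SE, n = 10), and p53 targets, 8 and 7 of 12. The p53 scores were 0.68 ± 0.80 in 6 of 8 libraries (adjusted permutation p = 0.0127) and 0.51 ± 0.80 in 6 of 10 (0.03). In 5 of the 8 runs with both labels exactly 1 of them had a p53 deviation above 0.5 (in 6 exactly 1 was above 0). Above 0.5 were 4 of 8 libraries of the former and 5 of 10 of Genistein. The inhibitor of NF-kB activation also raised the trophoblast factor gene Gcm1 (2.98 ± 0.22), Pde2a (2.82 ± 0.18), 7 of 9 trophectoderm genes, 6 of 11 FGF and ERK targets and 2 of 8 Nrf2 targets, Osgin1 at 0.95 and Nqo1 at 0.78, and Crxos (-1.78 ± 0.47), Myl7 (-1.57 ± 0.35) and Vldlr (-1.42 ± 0.30) fell. Of 6 NF-kB targets edgeR called 0 under it, with 3 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. Genistein raised Nkx2-9 (2.05 ± 0.23) and Enpp2 (1.92 ± 0.24), and Tceal5 (-1.83 ± 0.57) and Slc9b2 (-1.11 ± 0.35) fell.

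KAAD-Cyclopamine at 600 nM blocks and Purmorphamine at 130 nM activates Smoothened, the transducer of hedgehog signals. Their targets Gli1 and Ptch1 differed by -0.13 log2 (95% interval -0.59 to 0.33) and -0.17 (-0.49 to 0.14) between them. In edgeR 0 of 4 hedgehog targets were called for the pair or for either compound, with 0, 0 and 1 at an unadjusted p under 0.05 for the pair, KAAD-Cyclopamine and Purmorphamine, and 0 in limma-voom and in DESeq2. Purmorphamine raised Vrtn (1.26 ± 0.30, SE, n = 10), Wt1 (1.14 ± 0.23) and Pax8 (0.93 ± 0.25), all 3 of which also passed without the 4 libraries of doubted label. The pair differed in 48 genes, all lower under KAAD-Cyclopamine, including Arhgef33 (-2.49 ± 0.56) and Cnga3 (-1.76 ± 0.42). Without the 4 libraries of doubted label 3 genes differed, with Arhgef33 at -0.10, and limma-voom called 0.

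Kinase inhibitors with other targets were examined next. SB202190 at 1 uM, an inhibitor of p38 kinase, lowered Lefty1 (-2.20 ± 0.49, SE, n = 9) and Chst15 (-2.14 ± 0.40), and 4 of 8 Activin and nodal targets fell (list score -1.12 ± 0.69 in 9 of 9 libraries, adjusted permutation p = 0.0003, the smallest they can give). Lefty2 in the R1-labelled Activin A library with SB202190 was at 0.334 CPM. Dusp4 (1.06 ± 0.17), Glod5 (1.10 ± 0.20) and Slfn9 (1.08 ± 0.23) rose under it. Olomoucine at 30 uM, an inhibitor of cyclin-dependent kinases, raised Arsg (1.85 ± 0.13, SE, n = 10), Mlycd (1.63 ± 0.14) and Lonrf2 (1.34 ± 0.15), and Tmem92 (-3.29 ± 0.65) and the multi-copy genes Gm4312 (-3.12 ± 0.67) and Gm4301 (-3.02 ± 0.66) fell. All 3 Zscan4 genes (score -2.12 ± 1.33, adjusted permutation p = 0.0028) and 6 of 10 endoplasmic reticulum stress genes fell under Olomoucine, whereas edgeR called 0 of 12 p53 targets and 0 of 10 mitosis genes, with 7 and 5 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. Y-27632 at 20 uM, used under the R1 label alone, raised AA467197 (4.32 ± 0.27, SE, n = 5), Lrrc15 (3.56 ± 0.26), 6 of 7 FOXO targets, 5 of 10 endoplasmic reticulum stress genes and 7 of 9 trophectoderm genes. Gm9758 (-2.64 ± 0.68), Gcm1 (-2.52 ± 0.73), Pramel19 (-2.28 ± 0.67) and all 3 Zscan4 genes fell under it. Olig2 rose by 3.68 ± 0.83 but stood at -0.72 with the cluster as a term.

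Of 12 SRF and YAP targets edgeR called 0 under Y-27632, Src Inhibitor II at 10 uM and PF573228 at 100 nM, an inhibitor of focal adhesion kinase, with 4, 2 and 2 at an unadjusted p under 0.05. There limma-voom called 1 under Y-27632, and 0 under the other 2, and DESeq2 called 0. Pax8, a transcription factor gene of kidney and thyroid, rose under Src Inhibitor II (1.39 ± 0.23, SE, n = 8), PF573228 (1.3 ± 0.24, n = 8) and Wortmannin at 80 nM (1.20 ± 0.23, n = 10), an inhibitor of phosphoinositide 3-kinase. Src Inhibitor II also raised Aire (1.28 ± 0.23) and Myrf (1.11 ± 0.26) and lowered Tbx18 (-1.47 ± 0.43), Plagl1 (-1.18 ± 0.34) and Rnf144b (-1.12 ± 0.31). PF573228 raised Dleu7 (1.15 ± 0.19) and Myrf (0.98 ± 0.26) and lowered Fut2 (-1.97 ± 0.53), Bmp7 (-0.89 ± 0.25) and Epb41l4b (-0.72 ± 0.20). Wortmannin raised Pdyn (1.08 ± 0.16) and Casq1 (1.01 ± 0.17) and lowered Gpnmb (-1.60 ± 0.55), Lrrc15 (-1.58 ± 0.43) and Trpm1 (-1.51 ± 0.48). Of 7 FOXO targets edgeR called 0 under Wortmannin, with 3 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2.

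Of the remaining small molecules, BAPTA-AM at 4 uM, a calcium chelator, raised 6 of 11 germline genes (score 0.58 ± 0.41 in 9 of 10 libraries, adjusted permutation p = 0.000514) with Cyp2t4 (2.15 ± 0.17, SE, n = 10), the germ cell factor gene Taf7l (2.02 ± 0.23) and Ttll11 (1.66 ± 0.14), and lowered Cyp1a1 (-1.34 ± 0.44), Treml2 (-1.12 ± 0.20) and C1s2 (-1.05 ± 0.22). DAPT at 2.5 uM, a gamma secretase inhibitor, raised Otx2 (1.21 ± 0.25, SE, n = 9), Slc16a3 (1.14 ± 0.22) and Aire (1.06 ± 0.23), and 5 of 8 fibroblast markers fell (6 adjusted over the list alone) with Col1a2 (-3.14 ± 0.81), Tnc (-2.89 ± 0.93) and Col6a1 (-2.83 ± 0.72). The fibroblast score fell mostly in R1-labelled bFGF (0.513, block mean 2.64) and Activin A (0.546, block mean 2.19) and JM8.N4-labelled retinoic acid (0.151, block mean 1.29). That last library was 1 of 4 in cluster 2 in its block, which were all at 0.271 or less. In BMP4 the score lay above the block mean under both labels (0.491 against 0.40 for R1, 1.613 against 1.40 for JM8.N4). Since this score varies widely within blocks, the fall may not be due to DAPT. Of 4 Notch targets edgeR called 0 under DAPT, with 3 at an unadjusted p under 0.05, 1 lower adjusted over the list alone, 0 in limma-voom and 1 in DESeq2. Valproic Acid at 25 uM raised all 3 Zscan4 genes, the multi-copy genes Gm9758 (1.62 ± 0.26, SE, n = 10), Zscan4b (1.56 ± 0.31) and Zscan4e (1.55 ± 0.32), and 5 of 12 SRF and YAP targets (6 adjusted over the list alone), and lowered Trpm1 (-1.57 ± 0.49), Hoxc13 (-1.05 ± 0.31) and Rasgef1a (-1.01 ± 0.30).

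Bix01294 at 250 nM, an inhibitor of a histone methyltransferase, raised the AP-1 factor gene Fosl2 (1.61 ± 0.27, SE, n = 8), Maff (1.58 ± 0.17), Prss23 (1.64 ± 0.35) and 4 of 10 endoplasmic reticulum stress genes, and lowered Rec8 (-0.73 ± 0.22), Ifitm7 (-0.68 ± 0.15) and a gene without a symbol (Entrez 237250, -1.20 ± 0.34). Of 8 fibroblast markers 3 rose under it (5 adjusted over the list alone), and Prss23 stood at 0.22 with the fibroblast score as a term. Telomerase Inhibitor 3 at 2 uM raised Cyp2b23 (1.43 ± 0.22, SE, n = 7), Cntfr (1.13 ± 0.25) and Pax6 (1.09 ± 0.21) and lowered Acta2 (-2.61 ± 0.89), Pramel39 (-2.50 ± 0.75), Gm13871 (-2.24 ± 0.73), 6 of 14 naive genes and 2 of 12 p53 targets, Cdkn1a at -1.12 and Trp53inp1 at -0.64. Acta2 stood at -0.54 under it with the fibroblast score as a term. The inhibitor of Myc dimerisation, at 12.5 uM, raised Cpt1b (1.15 ± 0.22, SE, n = 7), Pdyn (0.85 ± 0.19) and a gene without a symbol (Entrez 545859, 1.09 ± 0.23). Of 11 Myc targets edgeR called 0 under it, with 0 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. For 11 germline genes edgeR called 0 under Valproic Acid and under Bix01294, with 1 each at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2.

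Lists of stress and metabolism moved under a few small molecules. Of 9 cholesterol synthesis genes 3 fell under Docetaxel, 2 under BIO and 2 under Y-27632, with scores of -0.47, -0.39 ± 0.20 and -0.58 (adjusted permutation p of 0.00687, 0.00396 and 0.00351). Of 9 hypoxia and glycolysis genes 5 fell and 1 rose under BIO (score -0.53), and 3 fell and 2 rose under PD173074 (score -0.40). Heat shock genes fell under BIO (2 of 7) and Olomoucine (2 of 7) and rose under Wnt agonist (2 of 7), with scores of -0.35, -0.29 and 0.35. Of 3 metallothioneins 2 rose under Y-27632 (score 1.02) and 2 fell under Docetaxel (score -0.87). Aryl hydrocarbon receptor targets rose under Y-27632 and Wnt agonist, 3 of 5 each, and edgeR called 0 of 5 under Genistein, with 1 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. Under BAPTA-AM 0 of 10 endoplasmic reticulum stress genes and 0 of 3 metallothioneins were called in edgeR, with 1 and 1 at an unadjusted p under 0.05 and 0 in limma-voom and in DESeq2. Counts of called list members given alone for small molecules were equal when adjusted over the list alone.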

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

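Tests chosen only after the result was seen were those on BMP4 or retinoic acid regulation, on correct line labels and the primitive endoderm difference, on the Y chromosome, on the runs with the inhibitor of NF-kB activation and Genistein, on the CHIR99021 library in BMP4, on the response of fibroblast markers to Activin A or bFGF, and every count of other divisions of the libraries.

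The responses to all 4 morphogens differed between the line labels, with 414 genes for Activin A, 1544 for bFGF, 3276 for BMP4 and 3574 for retinoic acid in tests of the difference itself. Other divisions of the line labels within each morphogen, counted by limma on log2(CPM + 1), reached the real count in 1 of 100 each, the real one. A chance division of single libraries can thus be excluded. Each line label of a morphogen is 1 run of libraries, and the divisions mix the runs, so a difference between runs is not excluded. For Activin A the real count was 74 and the highest other 0, for bFGF 549 and 113, for BMP4 2005 and 79, and for retinoic acid 2230 and 7. The differences follow the labels as given, and with the cluster as a term BMP4 gave 680 and retinoic acid 297. For Activin A limma-voom gave 225, the fit without small-molecule terms 172 and the small molecules present in every block 76, and for bFGF the last gave 782 and the fibroblast score as a term 956.

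Of 40 morphogen-named genes 16 had a response that differed between the labels, R1 minus JM8.N4. With bFGF the differences were 5.20 ± 1.78 log2 (SE, adjusted p = 0.0124) for Lox, 4.98 ± 1.3 for Col1a2, 4.45 ± 1.02 for Col1a1, 3.85 ± 0.83 for Tnc and 3.82 ± 0.90 for Dcn. The iron exporter gene Slc40a1 differed by 1.14 ± 0.42 and Zfp36l3 by 1.95 ± 0.62 with bFGF. With BMP4 Gata2 differed by 4.65 ± 0.56, Id2 by 2.87 ± 0.32 and Msx2 by 1.19 ± 0.49. In the other direction with BMP4 were Col3a1 at -4.00 ± 1.33, Cyp26a1 at -3.94 ± 0.97, Dcn at -2.72 ± 1.18 and Ccdc136 at -1.78 ± 0.25. With retinoic acid Otx2 differed by -1.89 ± 0.75 and Col3a1 by -5.24 ± 1.39.

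The first pattern weighed is the 71 libraries whose Eif2s3y group is at odds with the line label, which lie mostly in BMP4 and retinoic acid and include the 3 JM8.N4-labelled mock libraries. Regulation by BMP4 or retinoic acid whatever the small molecule is argued against by 4 of 4 blocks that hold libraries of both groups. Regulation that depends on the small molecule but acts alike under both labels is argued against by 23 of 38 small molecules whose groups were crossed between the labels. Loss of the Y chromosome as the only cause is argued against by 29 of the 31 splitting genes, which lie on other chromosomes. Such a loss beside other differences stays open, since 2 of the splitting genes are Y-linked. A mislabelled sample stays open for the treated libraries, since 933 further genes that differ between the labels in N2B27 and bFGF placed 98.5% of the libraries at odds (67 of 68) on the side of their group, and 55 of 55 of the others outside N2B27 and bFGF. These genes also placed all 6 mock libraries, 3 of them labelled JM8.N4, on the side of the higher Eif2s3y group. A difference between the lines under correct labels could not be decided by the 933 genes, which placed 1 of the 68 on the side of its line label. They were picked where line label and group coincide, so they may mark the group rather than the line. Line labels in BMP4 and retinoic acid may be wrong for many libraries, a hypothesis from the same data. Wrong line labels alone are argued against as the cause of the primitive endoderm difference, since in the higher Eif2s3y group the lowest score of JM8.N4-labelled BMP4 or retinoic acid libraries lay 2.22 above the highest of R1-labelled ones, and what else sets them apart was not tested.

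The second pattern is that responses of p53 or Wnt targets sit under another small-molecule label in some runs. In BMP4 under the JM8.N4 label the CHIR99021 library had a Wnt deviation of -0.12, where the other 9 had 1.49 or more, and the Purmorphamine library had 1.4, where its others had 0.29 or less, which argues against Purmorphamine raising Wnt targets there. In retinoic acid under the R1 label the p53 deviation was -0.33 for Wnt agonist (1 or more in its others) and 1.49 for Purmorphamine (0.09 or less in its others). Dependence on the morphogen is argued against by 3 of 8 pairs of libraries with 1 small molecule and morphogen in which 1 line label alone had a p53 deviation above 0.5, unless the lines themselves respond differently, which was not tested. A mislabelled sample stays open, with exactly 1 of the inhibitor of NF-kB activation and Genistein above 0.5 in 5 of 8 runs, both in 1 and neither in 2, and with exactly 1 above 0 in 6 and both in 2.

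The third pattern is that fibroblast markers differ between libraries of 1 line and morphogen. In JM8.N4-labelled BMP4 libraries the score was 0.584 or less in cluster 2 and 1.304 or more in cluster 1. In JM8.N4-labelled retinoic acid libraries it was 0.271 or less and 0.936 or more. Under the R1 label the clusters overlapped in these morphogens, and R1-labelled bFGF libraries, all in cluster 1, ran from 0.27 to 4.54. A response to Activin A or bFGF whatever the small molecule is argued against by 31.9% of the R1-labelled libraries with either (15 of 47) that lay below the R1-labelled N2B27 mean of 1.03, and library size by a correlation of 0.09 within blocks. Low libraries included PD173074 (0.463, a library whose small-molecule label is in doubt), SU5402 (0.514) and Genistein (0.448) in bFGF and SB202190 (0.41) in Activin A, as a response blocked by an inhibitor would give. Without these 4 it was 11 of 43. DAPT (0.546 and 0.513), Olomoucine (0.939 and 0.274) and SU5402 (0.471 and 0.514) were low in Activin A and bFGF alike, whereas Genistein stood at 3.422 in Activin A. The 11 also included BAPTA-AM (0.45), the inhibitor of NF-kB activation (0.551) and Purmorphamine (0.565) in Activin A. In bFGF the inhibitor of Myc dimerisation (0.401) was among them. The 4 were picked from the low libraries, so they carry little weight. A response that depends on the small molecule stays open. RNA from other cells, such as feeder fibroblasts, could not be decided, since of 12 further fibroblast genes 7 were at least 2-fold higher in mock than in N2B27, with Ccl2 at 7.91, Pdgfrb at 3.82 and Fbln5 at 3.18 log2 but Pcolce at -0.36 and Mfap5 at -0.66, and 11 of the 12 were tested, between the 10 that such RNA would need and the 6 that would argue against it. The protocol describes culture without feeder cells, and cells differentiating in culture were not tested as a source.

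Among 73 list scores past the threshold 13 had a library far from the others of its small molecule, where chance gives about 3.6, so single ones carry little weight. The number given is the gap to the nearest library as a share of the range. For CHIR99021 the JM8.N4-labelled BMP4 library stood apart in mesendoderm (0.508), neural (0.479), Wnt (0.505) and hedgehog (0.53) scores. For Wnt agonist the R1-labelled retinoic acid library stood apart in Notch (0.551), p53 (0.767) and Myc (0.574) scores. For PD173074 the R1-labelled bFGF library stood apart in formative (0.573) and Notch (0.621) scores. Its profile correlated at 0.146 with that of PD173074, which ranked 13 of 24, where the other 9 libraries had 0.732 or more. For Bix01294 the R1-labelled bFGF library did so in endoplasmic reticulum stress (0.63), and for Olomoucine the JM8.N4-labelled Activin A library in trophectoderm (0.489). For Y-27632 the R1-labelled Activin A library stood apart in mitosis (0.714) and the R1-labelled bFGF library in metallothioneins (0.727). That Activin A library correlated at -0.001 with the profile of Y-27632, which ranked 15 of 24, where the other 4 had 0.645 or more, and it was the only R1-labelled Activin A library in the lower Eif2s3y group (5.414 CPM). The small-molecule labels of these 2 libraries are in doubt too, but both were kept, and Y-27632 gave 3177 genes without its Activin A library.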

How the results depend on the processing

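Tests chosen only after seeing the data were those with trended dispersions, a cluster term, single clusters, a fibroblast score term, and without libraries of doubted label. Over 19 results and 236 comparisons with an alternative, 173 counts stayed within 1.5 times and 63 did not, and the cause was not tested unless given. DESeq2 size factors and no filter on low counts moved none of the results they were run on beyond 1.5 times, and they were not run on the list scores. Of 972 named gene values, size factors left 969 on their side of the threshold, no filter 956, and limma-voom 885, and the DESeq2 Wald test did so for 830 of the 876 it covered. The sign of 1 called value reversed, the BMP4 difference between line labels for T (2.10 in limma-voom), and 49 uncalled values changed sign. Depth limits genes near 1 CPM, where libraries of 8178141 counts hold few reads.

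No fold minimum raises counts by its construction, to 4250 for Activin A, 1066 for bFGF, 1546 for BMP4, 8477 for retinoic acid, 10651 for N2B27 against mock, 9058 for the treated line labels, 1748, 6921, 10559 and 11025 for the line differences in response to Activin A, bFGF, BMP4 and retinoic acid, 52 for LDN-193189 against dorsomorphin, 4901 for CHIR99021 against BIO, 3040 for PD173074 against SU5402 and 83035 for all small molecules. The small molecules present in every block gave 24 for bFGF, 96 for BMP4, and 76 and 782 for the line differences in Activin A and bFGF, over fewer libraries. Without small-molecule terms bFGF gave 43 and the Activin A line difference 172. In limma-voom bFGF gave 34, the Activin A line difference 225, KAAD-Cyclopamine against Purmorphamine 0, the BMP interaction 12 and the FGF interaction 16, and DESeq2 gave 2 between the mock labels. Trended dispersions gave 3 for KAAD-Cyclopamine against Purmorphamine.

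R1-labelled libraries alone gave 782 for bFGF, 1260 for BMP4 and 47 list scores, and JM8.N4-labelled ones 183, 1267 and, for retinoic acid, 2989, where agreement of both labels is no longer asked. Dropping that agreement alone, with both labels kept, gave 256 for BMP4. Within each label most BMP4 and retinoic acid libraries lay in the other cluster than the N2B27 ones. Their single-label counts therefore also hold differences between the clusters. Cluster 1 alone gave 634 for Activin A, 807 for bFGF and 376 for BMP4, and cluster 2 alone 163 for bFGF and 234 for BMP4. With the cluster as a term the FGF interaction gave 149, and the line differences in response gave 680 for BMP4 and 297 for retinoic acid, with 430 and 163 of the genes shared. With the fibroblast score as a term Activin A gave 66, bFGF 12, the bFGF line difference 956 and the FGF interaction 0. Without the 71 libraries at odds with their line label BMP4 gave 91, CHIR99021 against BIO 947, PD173074 against SU5402 507 and KAAD-Cyclopamine against Purmorphamine 1, and without the 4 of doubted small molecule the last gave 3.

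Leaving out single libraries gave 2777 to 2801 for N2B27 against mock and 0 to 1 between the mock labels, with 1 without R1-labelled mock 1. LDN-193189 against dorsomorphin ranged from 4 to 169, with 10, 5, 9, 7 and 12 without the LDN-193189 library of bFGF, Activin A, N2B27, BMP4 and retinoic acid, and 4, 169 and 5 without the dorsomorphin library of Activin A, N2B27 and retinoic acid. The BMP interaction ranged from 15 to 18, with 15 without dorsomorphin, and the FGF interaction from 0 to 296, with 0 without R1-labelled PD173074, 18 without R1-labelled SU5402 and 296 without JM8.N4-labelled SU5402. Among single small molecules dorsomorphin ranged from 48 to 477 and Y-27632 from 1661 to 3177, with 48, 214 and 101 for dorsomorphin without Activin A, bFGF and retinoic acid, and 1661 for Y-27632 without BMP4.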

Other observations

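Every count of other divisions of the libraries given here was a test chosen only after the result was seen, and so was the comparison of small-molecule profiles.

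Under several small molecules, scores of gene groups outside their usual target differed from those under the other small molecules. Whether they act on these groups directly was not tested. PD173074 raised NF-kB targets, 3 of 6 (score 0.42), and 1 of 4 Notch targets (score 0.43), and BIO raised 2 of 6 NF-kB targets (score 0.48). SU5402 raised 2 of 4 hedgehog targets (score 0.64, adjusted permutation p = 0.0072), which CHIR99021 lowered, 2 of 4 (score -0.56, 0.006). CHIR99021 lowered 4 of 6 neural genes and raised 1 (score -0.84). Myc targets had lower scores under Docetaxel (-0.33), Y-27632 (-0.31), BIO (-0.25), PD173074 (-0.24) and Wnt agonist (-0.22).

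Profiles over 2000 genes placed 82 treated libraries nearest to the mean profile of their own small molecule in other blocks, among the 24 small molecules, where chance gives 8.4. Median correlations between single libraries across genes, which are not independent replicates, were 0.77 between Docetaxel and Wnt agonist, with 0.82 and 0.77 within each. They were 0.62 between CHIR99021 and BIO (0.67 and 0.74 within), 0.25 between PD173074 and SU5402 (0.69 and 0.34 within), 0.02 between LDN-193189 and dorsomorphin (0.23 and 0.09 within), 0.14 between the inhibitor of NF-kB activation and Genistein (0.04 and 0.01 within) and 0.15 between KAAD-Cyclopamine and Purmorphamine (0.19 and 0.16 within).

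Mock libraries differed from each other by more than counting error, which gives a mean chi-square per gene near 1, with 1.48 to 2.55 over 15 pairs. It was 1.86 over the 6 pairs of the same line label and 1.92 over the 9 pairs across labels. Over 2011 pairs of treated libraries within a block it ran from 1.99 to 273, with a median of 49.6. For the mock labels the 10 divisions of 6 libraries are too few for a share under 0.05, and 10 of 10 reached the real count of 0, with a highest other of 1.

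Other divisions of the libraries were counted by limma on log2(CPM + 1), with 100 for each result and the real one included. Chance can be excluded, with 1 of 100 as large, for Activin A (real 67, highest other 14), retinoic acid (729 and 14), the treated line labels (93 and 4), all small molecules together (15316 and 1892) and CHIR99021 against BIO (934 and 849). Chance here means a chance division of single libraries. The divisions break up runs or places in a run, so effects of these are not excluded. For bFGF (5 and 8), BMP4 (37 and 62) and PD173074 against SU5402 (627 and 1185) 2 of 100 were as large. Chance is not taken as excluded there, since another division called more genes and the shares are not adjusted over the results. It cannot be excluded for LDN-193189 against dorsomorphin (6 of 100, 11 and 1707) or for the number of genes in the BMP interaction (9 of 100, 15 and 429). For the BMP targets of that interaction it can be excluded, with 1 of 100 as large (5 of 9 called lower, highest other 3), and Id1 differed by -3.60 ± 0.39 log2 (SE, adjusted p = 9.23e-13). For N2B27 against mock 1 of 100 was as large (1706 and 39), but the mock libraries may be technical replicates, so nothing follows about chance there. For the FGF interaction and KAAD-Cyclopamine against Purmorphamine limma called 0 in the real division, which every division reaches (100 of 100, highest others 118 and 976), so nothing follows about chance there. Divisions that call many more genes than the real one may reflect a structure of the libraries, such as a division that gathers those of a strong small molecule. This was not tested.

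For single small molecules chance can be excluded with 1 of 100 as large for the inhibitor of NF-kB activation (real 705, highest other 269), BIO (2299 and 222), CHIR99021 (924 and 358), Docetaxel (3699 and 554), Genistein (136 and 89), LDN-193189 (61 and 45), Olomoucine (920 and 285), PD173074 (996 and 663), Telomerase Inhibitor 3 (397 and 314), Wnt agonist (2588 and 194) and Y-27632 (1449 and 806). The share was 2 of 100 for DAPT (89 and 562), SB202190 (354 and 405), SU5402 (104 and 770), Valproic Acid (85 and 131) and Wortmannin (72 and 394). It was 3 of 100 for BAPTA-AM (150 and 660) and 4 of 100 for Bix01294 (81 and 744). These shares are not adjusted over the 24 small molecules. The divisions also break up the fixed place of a small molecule in each run, so an effect of place is not excluded. Chance is not taken as excluded where the share is 2 or more, since another division then called at least as many genes. It cannot be excluded for dorsomorphin (5 of 100, 197 and 634) and Src Inhibitor II (11 of 100, 10 and 544). For the inhibitor of Myc dimerisation, KAAD-Cyclopamine, PF573228 and Purmorphamine limma called 0 in the real division, which every division reaches (100 of 100, highest others 1799, 514, 634 and 201), so nothing follows about chance there. In edgeR these 4 gave 17, 0, 98 and 124 calls. DAPT, SU5402, Bix01294, dorsomorphin, BAPTA-AM and Src Inhibitor II have a highest other several times the real count, for a reason that was not tested.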
